A study of Mus musculus with 8 samples.

How the data were processed

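MicroRNA levels were measured in CD4+ and CD8+ T cells that had been sorted by flow cytometry from the liver and the mesenteric lymph nodes of male C57BL/6 mice fed a high-fat or a normal diet for 12 weeks. Per the labels, RNA of 6 mice was pooled in equal amounts for each sample, total RNA was purified with a mirVana miRNA Isolation kit, and each pool was labelled with the miRNA Complete Labeling and Hyb kit in 1 colour (Cy3). The 8 combinations of diet, tissue and cell type had 1 array each, so no group had a replicate. Groups were taken from the sample titles. The labels give an age of 7 weeks, without saying whether that was the age at the start of the diet.

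Per the file headers, the arrays were Agilent mouse miRNA arrays (design 038112) read with Agilent Feature Extraction 10.7.3.1, and all 8 lay on 1 slide and were scanned once. CD4 arrays occupied slide row 1 and CD8 arrays slide row 2. Columns 1 to 4 held, in this order, high-fat node, normal-diet node, high-fat liver and normal-diet liver. Cell type and slide row therefore cannot be told apart, nor can slide column and the combination of diet and tissue. Each array had 49324 spots, of which 47160 measured 1179 miRNAs through 2982 probes and 2164 were controls. Each miRNA had 40 spots and 1 to 4 probes. Of the miRNAs, 1122 were of the mouse and 57 of mouse viruses.

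The deposited scanner files give the intensity of each spot on a linear scale. Per the file headers, the processed intensity is the spot signal minus a spatially detrended background (background method 7), with no scaling between arrays. The deposited flags, of another kind than a measurement (0 or 1), mark spots that are outliers, saturated or well above background, and miRNAs that the software called detected. The authors' deposited table holds log2 values for 1200 features. Set against the scanner files, each of its columns equals log2 of the software's total gene signal minus log2 of that array's 90th percentile, to within a spread of at most 1.67e-05. Its scale, centring and direction were thus recovered from the values and are not stated in the labels. Its column medians lay between -8.58 and -4.91, because most features stood at the lowest value of their array.

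The main values were made from the processed intensities. Outlier spots (1875 to 2221 per array) and control spots were left out, the remaining spots of a probe were averaged, and the probes of a miRNA were summed on the linear scale. Each array was scaled to the 75th percentile of the 88 mouse miRNAs detected on all 8 arrays. The 5th percentile of the scaled detected signals (2.87 on the log2 scale) then served as a floor, and log2 was taken. No spot was saturated. Tests covered the 184 mouse miRNAs that the software called detected on at least 4 arrays, out of 315 detected on any array. Values at the floor have no order among themselves.

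Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). The additive fit held diet, tissue and cell type, with 4 residual degrees of freedom and 18.0 prior degrees of freedom. Each of the 3 interactions was added alone, leaving 3 residual degrees of freedom. An alternative fit with all 3 left 1 residual degree of freedom, so its calls rest on little residual variation. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Since each group is 1 pooled array, these p-values rest on how far arrays depart from the fit, not on how mice vary. With 18.0 prior against 4 residual degrees of freedom, the variance used for a miRNA comes mostly from the other miRNAs. A p-value therefore does not measure how well the 4 matched differences of that miRNA agree. A two-sided sign-flip test on 4 pairs cannot give a p below 0.125. Differences between the single high-fat and normal-diet arrays of a tissue and cell type have no test and are given with the standard error between spots, which covers measurement error on the array only. The number of arrays limits the precision of all values.

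The design, the lists, the rule for named miRNAs and the first group of alternative settings were fixed before the data were examined. Named were up to 12 higher and 12 lower miRNAs per effect with the largest differences among those past the threshold and going one way in all 4 matched pairs. With fewer than 5 such miRNAs, the 5 highest and 5 lowest by moderated t were named as values. Up to 4 per direction were named for an interaction. For a pair of single arrays these were the 4 highest and 4 lowest differences among miRNAs detected on both arrays and above the median level, and up to 3 detected on 1 array only. List members could be named with their list. MiRNAs named outside this rule are marked as chosen after their values were seen.

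A miRNA detected on no array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the brighter group against the mean, over the dimmer arrays, of the highest of the array's lowest detected signal, the miRNA's own signal and the common floor. The floor was added to this rule after the values had been seen, to keep the bounds from being too large.

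Lists of miRNAs were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, for lists of at least 3 tested members. The 11 tested lists were the let-7 family, miR-17~92 and its paralog clusters, the miR-15/16, miR-29 and miR-30 families, the miR-23/27/24 clusters, T cell activation and effector, naive and resting T cell, regulatory T cell, pan-leukocyte, and fatty liver literature. MiR-106a-5p and miR-17-5p share 1 feature on the array and were counted once. For pairs of single arrays, the list median was placed among 10000 random lists of the same size matched on mean level. The random lists were not matched on probe GC content or length. Their members were drawn at random, while members of a family can move together (estimated correlation 0.95 for let-7 and 0.85 for miR-17~92 in the additive fit). A percentile is therefore not a p-value. Markers of hepatocytes, myeloid cells, erythrocytes and platelets, endothelium, stroma and stellate cells, and epithelium and bile ducts were looked up but had under 3 tested members each.

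Tests were checked on simulated data with 36 changed of 184 miRNAs in 20 simulations per comparison. A log2 change of 1, 2 or 3 was recovered in 7.92%, 50.4% and 86.7% of cases for diet, in 8.75%, 53.8% and 81.7% for tissue, and in 11.3%, 64.6% and 90.8% for cell type. For the diet by tissue interaction the shares were 2.92%, 7.08% and 39.6%. Between 0.169% and 0.743% of unchanged miRNAs were called. The simulated noise was drawn independently for each miRNA and array, without the structure that miRNAs share on the real arrays. The recovered and called shares therefore need not hold for these data.

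The first group of alternative settings held scaling to the percentile over all miRNAs, quantile normalization, normexp background correction with an offset of 50, the software's total gene signal, the mean of log2 probe values, a floor at the 1st percentile, other detection filters, the authors' deposited table, a trended robust prior, all interactions in 1 fit, and leaving out each array. Chosen after the data were seen were scaling to labelling spike-ins, scaling to 23 miRNAs of the T cell lists, removal of a per-array trend on probe GC content and length, leaving out both normal-diet node arrays, and a fit with matched pairs as blocks. Chromosome positions are those of the probes' targets in genome build mm9, per the file headers and the probe annotation in the files. Positions within genes, exons or introns were not analysed here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.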

Results

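MicroRNAs are short RNAs that repress messenger RNAs, and they were profiled here in T cells from a mouse model of nonalcoholic fatty liver disease (NAFLD). CD4+ helper and CD8+ cytotoxic T cells came from the liver and from the mesenteric lymph nodes, which drain the gut, of mice on a high-fat or a normal diet. Each of the 8 combinations of diet, tissue and cell type was 1 pool of 6 mice on 1 array, so no group was replicated. By tissue, diet and cell type, 4 arrays stood against 4. Detected mouse miRNAs numbered 213 of 1122 in high-fat node CD4 cells, 191 in normal-diet node CD4 cells, 165 in high-fat liver CD4 cells and 133 in normal-diet liver CD4 cells. In CD8 cells the numbers were 269, 180, 165 and 121 in the same order. The summed signal of all mouse miRNAs ran from 30960 in normal-diet liver CD8 cells to 211799 in high-fat node CD8 cells, and within each tissue and cell type it was higher on the high-fat array. The high-fat node CD8 array, with 269 and 211799, was the only one on which the software did not use the default effective feature size (0.827 against 0.6). Its labelling spike-in signal was also higher (log10 3.16 against 2.91 to 3.01), and its part in these numbers was not tested. The 10 brightest miRNAs held 57.5% to 72.4% of the signal of an array. Levels below are log2 signals scaled to the 75th percentile of 88 miRNAs detected on every array. Of the 184 tested miRNAs, 96 were undetected on at least 1 array, and differences that use such an array rest partly on signals not above background.

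**Figure D1:**
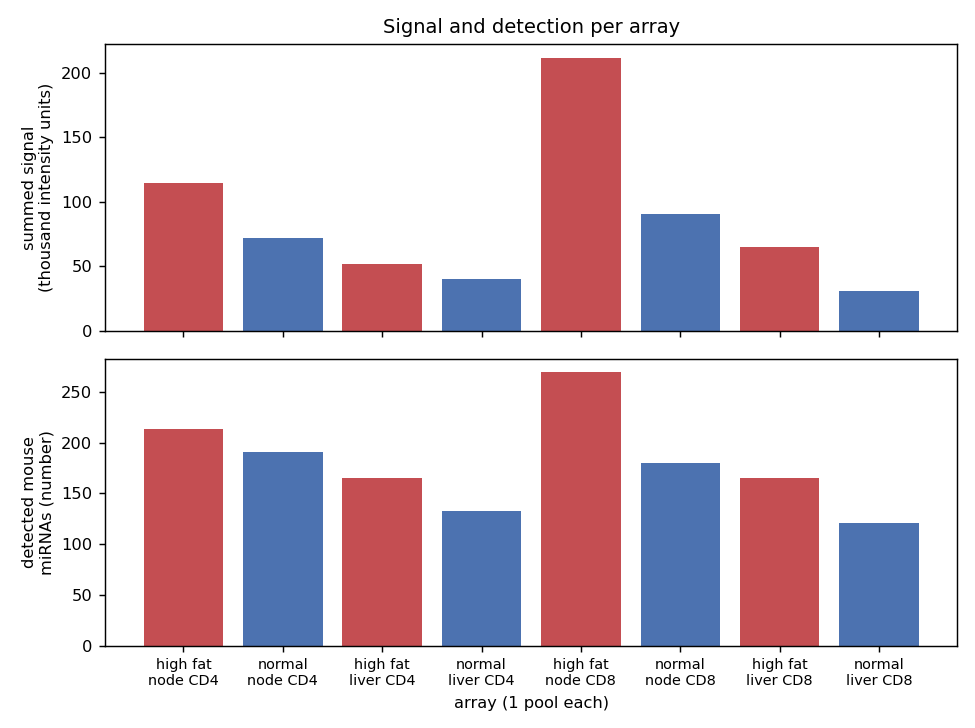
Summed signal of mouse miRNAs and number of mouse miRNAs detected on each of the 8 arrays, as bars from 0 with 1 pool of 6 mice per bar. The high-fat node CD8 array had the highest summed signal (211799) and the most detected miRNAs (269), and the normal-diet liver CD8 array had the lowest of both (30960 and 121).

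The first comparison asks how T cells of the liver differ from T cells of the mesenteric nodes. MiR-451, abundant in red blood cells, was detected on 4 of 4 liver arrays and on 0 of 4 node arrays, with mean levels of 7.41 ± 0.76 and 3.07 ± 0.40 (SD, n = 4 arrays each). Its log2 difference was 4.34 (SE 0.55, adjusted p = 1.41e-05), at least 20.05-fold. MiR-223-3p, best known from myeloid cells, rose from 3.27 ± 0.44 to 6.92 ± 0.49 (log2 difference 3.65, SE 0.55, adjusted p = 9.81e-05). MiR-22-3p rose by 3.11 on the log2 scale (SE 0.55, adjusted p = 0.000355), and miR-146a-5p, a brake on NF-kappaB signalling, by 2.81 (SE 0.61, adjusted p = 0.0021). MiR-5121 fell by 4.95 (SE 0.82, adjusted p = 0.00027) and miR-714 by 4.52 (SE 0.82, adjusted p = 0.000378). All 6 differed in the same direction in all 4 matched pairs of arrays, which the rule for named miRNAs requires and which is therefore no separate result.

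In all, 41 of 184 tested miRNAs were higher in liver cells and 39 lower. This split depended on the processing, with 7 higher and 54 lower under spike-in scaling, 12 and 50 with the authors' deposited table, and 29 and 12 under normexp. Over the tested miRNAs, the tissue difference correlated with probe GC content (Pearson r -0.51) and probe length (0.58). With the trend on both removed from each array, 43 miRNAs were called. Other miRNAs among the 12 with the largest rises were miR-5097 (3.08), miR-720 (2.96), miR-15a-5p (2.77), miR-27b-3p (2.62), miR-106b-5p (2.53), miR-27a-3p (2.51), miR-20a-5p (2.40) and miR-20b-5p (2.34), all log2 differences. Among the 12 with the largest falls, miR-3096b-5p (-4.36), miR-680 (-4.03), miR-1897-5p (-3.07), miR-3960 (-2.87), miR-706 (-2.82), miR-1224-5p (-2.80), miR-5128 (-2.71), miR-211-3p (-2.67) and miR-712-5p (-2.63) followed. The related miR-3096-5p (-4.20) can share signal with miR-3096b-5p. MiR-3096b-5p, miR-680, miR-1897-5p and miR-712-5p were detected on no liver array, so only bounds hold there: at least 11.2-fold, 10.2-fold, 6.87-fold and 3.36-fold lower. MiR-3096-5p was not detected there either. The probe annotation gave no chromosome position for miR-714 and miR-712-5p, whose probes had a mean GC content of 83.9% and 82.4%. In the mm9 build, the probe targets of miR-451 lay on chromosome 11 at 77886689 to 77886709, those of miR-223-3p on chromosome X at 93438224 to 93438244, those of miR-22-3p on chromosome 11 at 75277277 to 75277295, those of miR-146a-5p on chromosome 11 at 43187907 to 43187925, and those of miR-5121 on chromosome 7 at 52382339 to 52382354.

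Both normal-diet node arrays stood apart from the other 6. On the first principal component, with 74.3% of the variance, they lay at -19.1 (CD4) and -28.0 (CD8), and the other arrays lay between -1.21 and 13.1. Without these 2 arrays, an alternative chosen after they had been seen, limma called 5 miRNAs in place of 80. MiR-451 (4.05), miR-223-3p (3.88), miR-22-3p (2.69) and miR-500-3p (2.10) were higher in liver and miR-5105 (-1.82) was lower, the last 2 named after their values were seen. All but miR-500-3p were also among the 80 called with all arrays. The fit without the 2 arrays has fewer degrees of freedom, which by itself lowers the number of calls. MiR-5121, for example, had a difference of -2.27 there with an SE of 0.30, smaller than with all arrays, and did not pass (limma adjusted p = 0.0629). The drop to 5 therefore does not show that the other calls came from these 2 arrays. All 41 higher and 38 of 39 lower miRNAs kept their direction, while miR-149-3p, named after its value was seen, stood at 0, with the median difference going from 2.15 to 1.48 and from -2.34 to -0.88. Levels of miR-5121 were 10.23 and 12.99 on the normal-diet node CD4 and CD8 arrays, 6.16 and 6.88 on the high-fat node arrays, and 4.39 in high-fat liver CD8 cells, the only liver array that detected it.

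**Figure D2:**
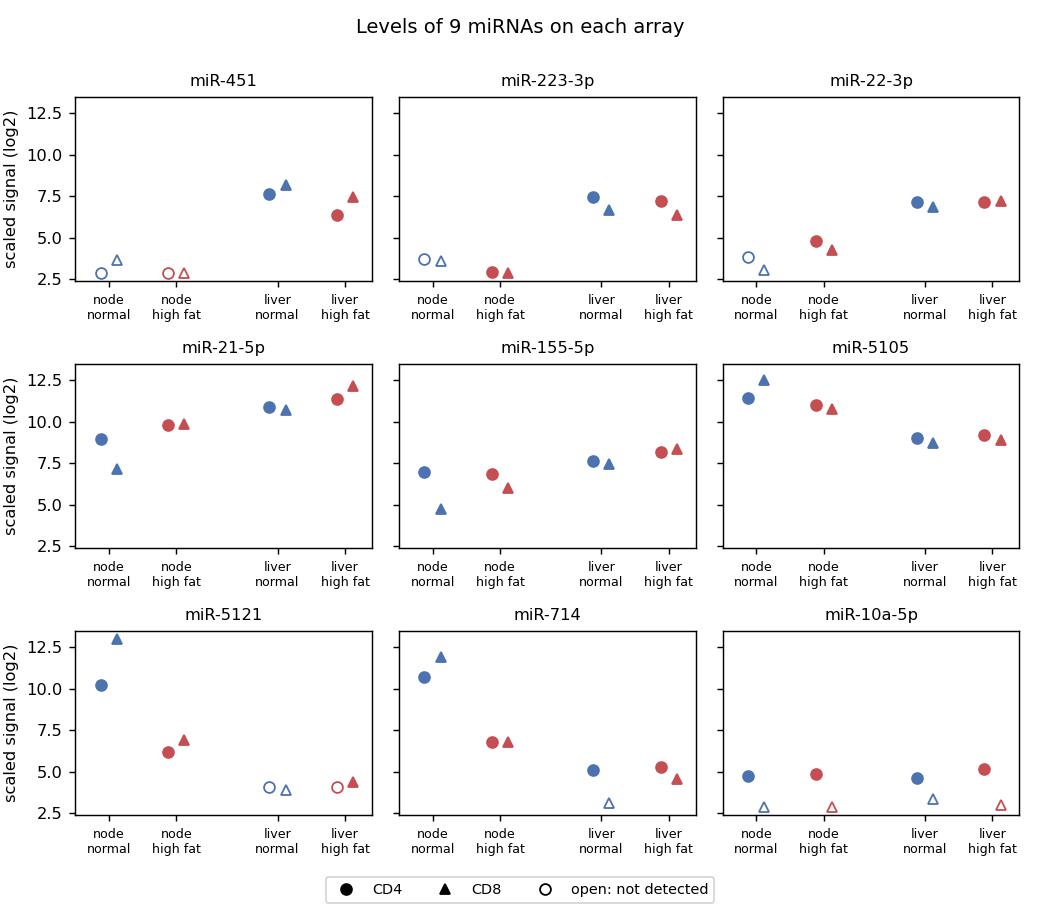
Scaled log2 level of 9 miRNAs on each of the 8 arrays, with normal diet in blue and high fat in red, circles for CD4 and triangles for CD8 cells, and open symbols where the miRNA was not detected. MiR-451 lies at 6.36 to 8.16 on the liver arrays and was not detected on the node arrays, and miR-5121 reaches 10.23 and 12.99 on the normal-diet node arrays.

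Of 11 lists of miRNAs, most with known roles in T cells, 7 passed camera as higher in liver cells against the other miRNAs, but none did with an estimated correlation (adjusted p = 0.370 to 0.437 with an estimated correlation). All 5 tested members of the miR-23/27/24 clusters rose, with a median log2 difference of 2.24. Of 13 miRNAs of the T cell activation and effector list on the array, 7 were detected on any array and 3 were tested. All 3 tested members rose, namely miR-146a-5p (2.81), miR-21-5p (2.32) and miR-155-5p (1.75), which need not stand for the rest of the list. Of miR-17~92 and its paralog clusters, which promote proliferation, 6 of 7 tested members rose (median 2.32), among them miR-106b-5p and miR-20a-5p. Of the regulatory T cell list 4 of 5 rose, which were those 3 activation miRNAs and the myeloid marker miR-223-3p (3.65), while miR-10a-5p (0.20) did not pass. The let-7 family had 4 of 8 past the threshold (median 1.43), and the naive and resting T cell list 3 of 7 (median 1.39). In the fatty liver literature list 6 of 8 rose and miR-370-3p fell by 2.49. Adjusted over the list alone, the numbers were 5 of 5 for miR-23/27/24, 3 of 3 for activation, 7 of 7 for miR-17~92, 4 of 5 for regulatory T cells, 5 of 8 for let-7, 4 of 7 for naive T cells, and 6 higher and 1 lower of 8 for fatty liver.

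The camera adjusted p of these 7 lists was 0.0185 for miR-23/27/24, 0.0433 for activation, 0.0171 for miR-17~92, 0.0288 for regulatory T cells, 0.0304 for let-7, 0.0497 for naive T cells and 0.0304 for fatty liver. In the same order these were adjusted p = 0.425, 0.425, 0.425, 0.370, 0.437, 0.425 and 0.370 with an estimated correlation. The miR-29 family (3 of 3 higher, median 2.15, adjusted p = 0.0560), the pan-leukocyte list (3 of 4, median 1.78, 0.0560), the miR-15/16 family (2 of 3, median 1.48, 0.0862) and the miR-30 family (1 of 3, median 1.22, 0.181) did not pass camera. Adjusted over the list alone, their numbers were 3 of 3, 4 of 4, 2 of 3 and 1 of 3. In fry, which asks only whether a list moves one way, all 11 passed, with the highest adjusted p at 0.046. No list passed camera without the normal-diet node arrays, where adjusted p ran from 0.0760 to 0.272. The median difference of all tested miRNAs was 0.32 and moved to -0.53 when arrays were scaled to labelling spike-ins and to -1.06 when scaled to T cell list miRNAs. Under the latter the miR-30 median became -0.25 and limma called 0 miRNAs (82 at an unadjusted p under 0.05).

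Markers of other cell types differed in how they moved with tissue. Beside miR-451 and miR-223-3p, the liver miRNA miR-122-5p had levels of 4.46, 6.14, 3.85 and 6.11 in high-fat CD4, normal-diet CD4, high-fat CD8 and normal-diet CD8 liver cells, and 7.26 in normal-diet node CD8 cells. It was detected on no other node array, and its tissue difference of 1.17 did not pass the test (SE 0.69, adjusted p = 0.164). MiR-148a-3p, the other tested miRNA of the hepatocyte list, rose in liver by 1.45 (SE 0.55, adjusted p = 0.0357), detected on 3 of 4 liver and 1 of 4 node arrays. Without the normal-diet node arrays it did not pass (1.67, SE 0.27, adjusted p = 0.0644), in a fit with fewer degrees of freedom. MiR-192-5p and miR-194-5p of the hepatocyte list were not tested. Both were detected on the high-fat node arrays only, near the floor. Their levels there were 2.97 and 3.46 in CD4 cells and 3.05 and 3.07 in CD8 cells. Of the marker lists, 4 of 7 hepatocyte, 3 of 6 myeloid, 1 of 3 erythrocyte and platelet, 1 of 2 endothelial, 0 of 10 stromal and 1 of 8 epithelial miRNAs on the array were detected on any array.

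The diet comparison asks which miRNAs differ in T cells of mice with fatty liver disease. By moderated t, the highest were miR-142-5p, a miRNA of all white blood cells, and 4 members of the miR-17~92 clusters. MiR-142-5p had mean levels of 6.63 ± 1.13 on high fat and 4.39 ± 1.76 on normal diet (SD, n = 4 arrays each), a log2 difference of 2.23 (SE 0.63, adjusted p = 0.0826). The liver CD4 pair differed by only 0.0089, within its spot SE of 0.08. The differences were 1.90 for miR-106b-5p, 1.66 for miR-20b-5p, 1.65 for miR-20a-5p and 1.61 for miR-19b-3p, with adjusted p from 0.126 to 0.139. MiR-142-5p, miR-106b-5p, miR-20a-5p and miR-20b-5p were detected on neither normal-diet node array, so their values are not measured folds. The lowest by moderated t had differences of -2.67 for miR-5128, -2.38 for miR-1897-5p, -2.12 for miR-5119 and -2.05 for miR-5110 (each adjusted p = 0.0826), and -2.33 for miR-712-5p (adjusted p = 0.126). MiR-1897-5p and miR-712-5p were detected on no liver array, so their liver part was not measured. In limma 0 of 184 miRNAs passed the threshold, and 46 had an unadjusted p under 0.05, 15 higher and 31 lower. The median difference of all tested miRNAs was -0.54 and became 0.48 under spike-in scaling, where limma called 43 higher and 0 lower. With all interactions in the fit, which leaves few residual degrees of freedom, it called 31 higher and 77 lower. With normexp it called 3 higher and 102 lower. Under normexp miR-106b-5p, miR-20a-5p and miR-20b-5p were not called, and their differences turned to -0.12, -0.15 and -0.042.

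As groups, 9 of the 11 lists stood above the other miRNAs on high fat by camera, but none passed with an estimated correlation (adjusted p = 0.313 to 0.317 with an estimated correlation). None of the 11 passed in fry (adjusted p = 0.243 to 0.351). Over the tested miRNAs, the diet difference correlated with probe GC content (Pearson r -0.40) and probe length (0.47). These list tests did not adjust for either. All 7 tested members of the miR-17~92 clusters had positive differences (median 1.61, camera adjusted p = 7.54e-05), of which 0 passed over all miRNAs and 4 adjusted over the list alone. All 3 members of the miR-29 family were positive (median 1.33, camera adjusted p = 0.00686), and all 3 passed adjusted over the list alone. The pan-leukocyte list had 4 of 4 positive (median 1.29, camera adjusted p = 0.00454), of which 2 passed adjusted over the list alone. Medians were 1.26 for miR-15/16 (camera adjusted p = 0.0087), 0.89 for naive T cells (0.00464), 0.84 for miR-30 (0.0377), 0.69 for let-7 (0.00686), 0.66 for miR-23/27/24 (0.0184) and 0.63 for activation (0.0454), with 0 members passing adjusted over the list alone in each of these 6 lists. Under normexp the medians of miR-17~92, miR-29, miR-30, miR-23/27/24 and activation became -0.12, -0.06, -0.63, -0.30 and -0.11, against a median of -0.89 over all miRNAs.

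The regulatory T cell list (median 0.51, camera adjusted p = 0.107, 0 members adjusted over the list alone) did not pass, and its median was -0.08 when scaled to T cell list miRNAs and -0.17 under normexp. The fatty liver literature list (median 0.62, camera adjusted p = 0.233) did not pass either. Its mean was slightly below 0 (-0.015), with 5 of 8 members positive. MiR-370-3p (-2.22), miR-122-5p (-2.08) and miR-223-3p (-0.52) were negative, and the first 2 passed adjusted over the list alone. Its median was -0.49 under normexp. Without the normal-diet node arrays limma called 0 miRNAs for diet (11 at an unadjusted p under 0.05), and no list passed camera (adjusted p = 0.165 to 0.884). The let-7 and miR-23/27/24 medians were then -0.20 and -0.024.

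Within single pairs of arrays, the fewest miRNAs differed between diets in liver CD4 cells. Of 132 miRNAs detected on both arrays there, 3 were higher and 2 lower by over 1 on the log2 scale. MiR-376b-3p (1.70), miR-1949 (0.69), miR-466g (0.59) and miR-3096b-3p (0.56) had the highest differences above the median level. MiR-451 (-1.29), miR-23b-3p (-0.80), miR-5622-3p (-0.57) and miR-342-3p (-0.55) had the lowest above that level. MiR-5709, miR-691 and miR-3070b-3p were detected only on the high-fat array, at least 3.03-fold, 2.69-fold and 2.60-fold higher. The typical standard error between spots was 0.06 on the log2 scale in this pair.

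In liver CD8 cells 13 miRNAs were higher and 27 lower by over 1 among 117. Above the median level, the highest values were those of miR-142-5p (2.08), miR-106b-5p (1.84), miR-19b-3p (1.76) and miR-29c-3p (1.74), and the lowest those of miR-466f-3p (-1.32), miR-466h-3p (-1.27), miR-574-3p (-1.25) and miR-669p-3p (-1.24). Let-7d-3p, let-7b-3p and miR-1943-3p were detected only on the normal-diet array, at least 3.98-fold, 3.97-fold and 3.51-fold lower on high fat. The median of the miR-17~92 clusters was 1.27, at percentile 99.4 of random lists, and those of the miR-29 family and the pan-leukocyte list were 1.47 and 1.20, at percentiles 97.6 and 99.2. In liver CD4 cells the miR-17~92 and miR-29 medians were 0.17 and -0.28, at percentiles 26.0 and 6.08. Scaling to spike-ins turned the liver CD8 counts into 67 higher and 0 lower, and normexp into 3 and 1.

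Differences between the diets over 1 were more frequent in node than in liver cells, but not under spike-in scaling when set against liver CD8 cells (67 of 117 there, 82 of 153 in node CD4 and 91 of 160 in node CD8 cells). In node CD4 cells 25 miRNAs were higher and 69 lower by over 1 among 153, and in node CD8 cells 25 and 111 among 160. These splits depended on scaling. Node CD4 had 45 and 45 with the percentile over all miRNAs, 44 and 41 with quantile normalization, 49 and 46 with the deposited table and 50 and 32 under spike-in scaling, and node CD8 had 47 and 44 under spike-in scaling and 38 and 58 with the deposited table. Above the median level, miR-32-3p (1.75), miR-142-3p (1.68), miR-468-3p (1.53) and miR-26b-5p (1.51) were highest in CD4 cells. MiR-690 (3.65), miR-26b-5p (3.47), miR-19b-3p (3.24) and miR-142-3p (3.23) were highest in CD8 cells. At those levels miR-5128 (-5.22), miR-5121 (-4.07), miR-714 (-3.94) and miR-3096b-5p (-3.40) were lowest in CD4 cells, and miR-5121 (-6.12), miR-1897-5p (-5.22), miR-712-5p (-5.16) and miR-714 (-5.13) in CD8 cells. Detected only on the normal-diet array were miR-376b-3p, miR-466o-3p and miR-5709 in CD4 cells, at least 91.9-fold, 43.7-fold and 15.0-fold lower on high fat. In CD8 cells these were miR-712-3p, miR-122-5p and miR-1940, at least 21.8-fold, 21.0-fold and 20.8-fold lower. The let-7 median was 0.70 in node CD4 and 2.42 in node CD8 cells, at percentiles 91.5 and 96.7, and that of miR-17~92 was 1.25 and 3.24, at percentiles 97.8 and 99.9. The random lists behind these percentiles were not matched on probe GC content. The slope of level per 10 percentage points of GC was 0.56 and 0.72 in normal-diet node CD4 and CD8 cells. On high fat it was 0.12 and -0.01. In liver CD4 and CD8 cells the let-7 medians were -0.20 and -0.14, at percentiles 1.1 and 72.8, with 7 and 6 of 8 members lower on high fat. Median differences over the pairs were 0.19, -0.31, -0.83 and -1.80 in liver CD4, liver CD8, node CD4 and node CD8 cells, and quantile normalization moved them to 0.00, -0.15, 0.07 and -0.72.

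**Figure D3:**
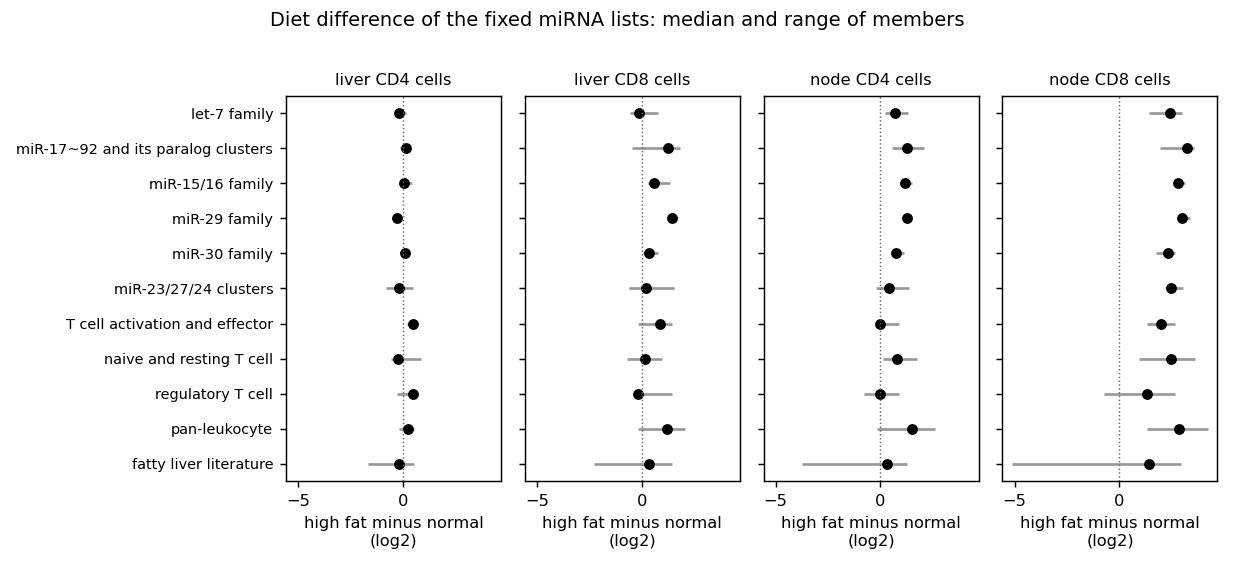
Median diet difference (high fat minus normal diet, log2) of 11 lists of miRNAs in each of the 4 pairs of single arrays, as points with lines from the lowest to the highest member. The miR-17~92 clusters have medians of 0.17 in liver CD4, 1.27 in liver CD8, 1.25 in node CD4 and 3.24 in node CD8 cells, before the scaling and background alternatives, some of which change the sign of list medians.

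Whether the diet difference itself depended on tissue was tested as an interaction. The miRNAs miR-714, miR-5121, miR-376b-3p and miR-188-5p were lower on high fat in both node pairs, and in liver cells they were not lower on average or could not be measured, with interaction values of 5.36, 5.36, 5.26 and 4.91 (liver minus node, log2) and adjusted p of 0.00185, 0.00185, 0.00523 and 0.00185. These are fitted values and not measured folds, because they rest partly on signals not above background: miR-188-5p was detected on no liver array, miR-5121 on 1 of 4 liver arrays, miR-714 not in normal-diet liver CD8 cells, and miR-376b-3p not in high-fat node CD4 cells. In node CD4 cells miR-188-5p had a level of 8.02 on normal diet and 5.02 on high fat, and in node CD8 cells 8.63 and 4.67. MiR-26b-5p (-2.54, adjusted p = 0.0329) and let-7g-5p (-2.41, adjusted p = 0.0373) went the other way, with diet differences of 1.51 and 3.47 for miR-26b-5p and 1.32 and 3.01 for let-7g-5p in node CD4 and CD8 cells. In liver cells these were -0.23 and 0.14, and -0.35 and -0.14. In all, 46 miRNAs had a positive and 2 a negative interaction. Of these 48, 19 were detected on no liver array, all of them positive, and 13 on all 8 arrays, and a fit of the 88 miRNAs detected everywhere called 8. The split was 35 positive and 25 negative with the percentile over all miRNAs, 31 and 17 with quantile normalization, and 7 and 13 with the deposited table. The number was 0 under spike-in scaling (55 at an unadjusted p under 0.05) and 0 without the high-fat node CD8 array (49).

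**Figure D4:**
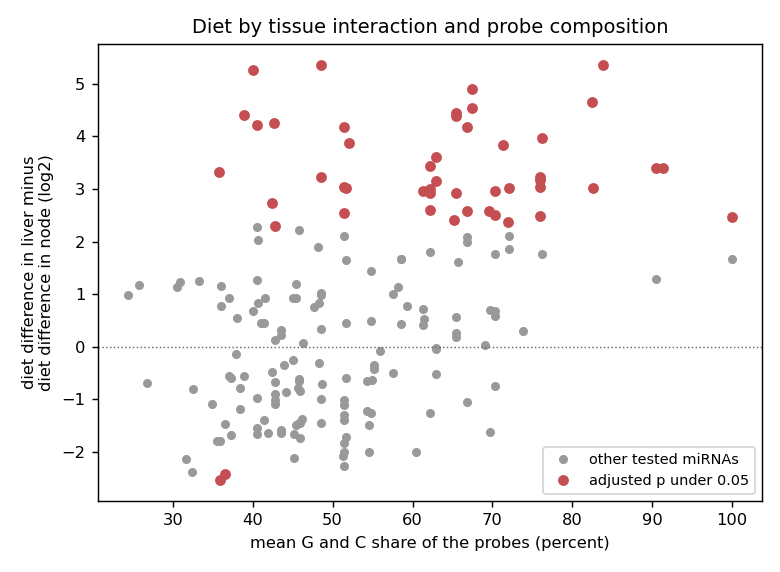
Diet by tissue interaction (log2, liver minus node) of 184 miRNAs against the mean GC content of their probes in percent, with miRNAs at an adjusted p under 0.05 in red. The 46 with a positive interaction had a median probe GC content of 65.5%, and the other tested miRNAs 47.9%.

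The last comparison sets CD8 against CD4 cells. MiR-10a-5p, a miRNA of regulatory T cells, was detected on 4 of 4 CD4 arrays and 0 of 4 CD8 arrays, with mean levels of 4.83 ± 0.23 and 3.03 ± 0.23 (SD, n = 4 arrays each). Its log2 difference of -1.80 (SE 0.55, at least 2.37-fold, lower in 4 of 4 pairs) did not pass adjustment in limma (adjusted p = 0.596). It passed with all interactions in the fit, which leaves few residual degrees of freedom. MiR-466o-3p (-1.11), miR-146a-5p (-1.07), miR-181a-5p (-0.96) and miR-669o-5p (-0.79) were the next lowest by moderated t and miR-1949 (1.10), miR-122-5p (0.94), miR-142-5p (0.91), miR-5117-5p (0.83) and miR-3096b-3p (0.79) the highest, each with adjusted p = 0.996. In limma 0 of 184 miRNAs passed, and miR-10a-5p alone had an unadjusted p under 0.05 (19 with all interactions in the fit). A number this low lies below the share of 0.05 that arises on average where nothing differs, so the test was conservative here. The additive fit leaves differences tied to diet by tissue in its residual variation. The lack of calls therefore does not show that CD4 and CD8 cells are alike. The probe targets of miR-10a-5p lay on chromosome 11 at 96178502 to 96178522.

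All 5 tested members of the regulatory T cell list had negative values in CD8 cells (median -0.76, camera adjusted p = 0.000347), of which 0 passed over all miRNAs and 1, miR-10a-5p, adjusted over the list alone. The list did not pass with an estimated correlation (adjusted p = 0.183 with an estimated correlation), nor in fry (adjusted p = 0.375). Its camera adjusted p was 0.114 under normexp, 0.0989 without the normal-diet node CD8 array and 0.118 without both normal-diet node arrays. The other 10 lists did not pass, with camera adjusted p from 0.0732 to 0.914, and none of their members passed adjusted over the list alone. In limma 0 miRNAs passed for the diet by cell type interaction and 0 for the tissue by cell type interaction, each with 0 at an unadjusted p under 0.05. With all interactions in the fit these last numbers were 43 and 18. These 2 tests were thus conservative as well, and 0 calls do not show that such interactions are absent. Without both normal-diet node arrays the cell type comparison had 0 calls and 7 at an unadjusted p under 0.05.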

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

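The tests of explanations in this part were chosen after the results were seen, as were the spike-in scaling, the removal of the probe trend and the fit without the normal-diet node arrays. The count of other splits of the arrays was fixed before.

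The fitted diet by tissue interaction passed limma's test for 48 of 184 miRNAs, of which 19 were detected on no liver array, so for these the liver difference was not measured. A fit of the 88 miRNAs detected on all arrays called 8. The named fitted values were 5.36 for miR-714, 5.36 for miR-5121, 5.26 for miR-376b-3p, 4.91 for miR-188-5p, -2.54 for miR-26b-5p and -2.41 for let-7g-5p (log2, liver minus node). They are not measured folds where signals were not above background: miR-188-5p was detected on no liver array, miR-5121 on 1 of 4 liver arrays, miR-714 not in normal-diet liver CD8 cells and miR-376b-3p not in high-fat node CD4 cells. Among 32 splits of the arrays only the real one gave as many calls, 1 of 32, with 5 as the highest other number. Most other splits overlap diet, tissue or cell type, which stay in the fit, and so had less power. The share of 1 in 32 is therefore not a chance level, and chance assignment was not excluded. The number was 0 without the high-fat node CD8 array and 10 without the high-fat node CD4 array. It was 0 under spike-in scaling, where the median interaction over all miRNAs moved from 0.55 to -0.00484. The 46 positive and 2 negative became 35 and 25 with the percentile over all miRNAs, 31 and 17 with quantile normalization, and 7 and 13 with the deposited table. The 46 miRNAs with a positive interaction had mean levels of 7.72 and 8.14 on the normal-diet node CD4 and CD8 arrays and of 4.31 to 4.88 on the other 6.

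These 46 miRNAs had GC-rich, short probes (median 65.5% GC and 13.5 bases, against 47.9% and 17.5 for the others), so a technical trend is a candidate explanation. With a linear trend on GC content and length removed from each array, their median interaction went from 3.20 (SD 0.86) to 2.60 (SD 1.20). Of the 46, 27 stayed past the threshold. This cannot decide the question, because the 46 were picked for high interactions in these same data, so high values remain in either case. A trend that is not linear was not tested, and a probe trend stays open. For a low RNA amount the values were mixed. By summed signal the 4 liver arrays were dimmer than the normal-diet node arrays. Their highest slope of level on GC content was -0.25 per 10 percentage points, against 0.56 and 0.72 on the normal-diet node arrays (SE of the difference 0.17). By the 75th percentile used for scaling, high-fat liver CD8, which had that slope, was brighter (512 against 401 and 379). The other liver arrays were dimmer by both measures, with slopes of -0.30 to -0.26. Within node cells the brighter high-fat arrays had the lower slopes (0.12 and -0.01), so a low RNA amount cannot be told apart there. Nonspecific binding cannot be told apart, because the median signal of 57 viral probes gave no clear order: the lower of the 2 normal-diet node arrays lay at -1.19 against the highest other array, while their mean was -3.95 and that of the others -4.23. The number of viral miRNAs called detected did differ, with 6 on each normal-diet node array and 2 or 3 on every other array. Slide column stays open as well, and so does an untested biological difference between the diets in node cells.

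Probes for viral miRNAs lie outside the comparisons, and 7 of the 57 viral miRNAs were detected. The murine gammaherpesvirus miRNAs mghv-miR-M1-2-3p and mghv-miR-M1-2-5p were detected on 8 and 8 arrays. Both normal-diet node arrays, and no other, detected mcmv-miR-M87-1 (2 arrays), mcmv-miR-m01-2 (2 arrays), mghv-miR-M1-11-5p (2 arrays) and mghv-miR-M1-8 (2 arrays), and both high-fat node arrays, and no other, detected mghv-miR-M1-6 (2 arrays). Whether these signals came from viral RNA or from nonspecific binding was not tested.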

How the results depend on the processing

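Spike-in scaling, scaling to T cell list miRNAs, removal of the probe trend, leaving out both normal-diet node arrays and the fit with matched pairs as blocks were chosen after the data were seen. Following list directions only for lists that passed camera was also chosen after the values were seen. Called lists changed sign relative to the median of all miRNAs in 2 of 213 comparisons for diet, 0 of 168 for tissue and 0 of 24 for cell type. The other lists did so in 36 of 237 comparisons for cell type, and in 0 of 48 for diet and 0 of 93 for tissue. Of the tested values, 1267 kept their direction and side of the threshold, 230 no longer passed it, 52 passed it newly and 10 reversed. The cause was not tested unless it is given.

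Diet calls, 0 of 184, were 105 under normexp (3 higher, 102 lower), 1 with the authors' deposited table, 43 under spike-in scaling, 4 among the 88 miRNAs detected on all arrays and 108 with all interactions in 1 fit (31 higher, 77 lower). Tissue calls, 80 (41 higher, 39 lower), were 41 under normexp, 0 when scaled to T cell list miRNAs, 43 without the probe trend, 42 among the 88 (fewer tested), 13 among all 315 miRNAs detected on any array, 134 with all interactions and 5 without both normal-diet node arrays, where the median of the higher calls went from 2.15 to 1.48 and of the lower calls from -2.34 to -0.88. The split of tissue calls was 34 higher and 49 lower with the total gene signal, 31 and 45 with the mean of log2 probe values, 12 and 50 with the deposited table, 7 and 54 under spike-in scaling, and 29 and 12 under normexp. The fit without both normal-diet node arrays has fewer degrees of freedom, which by itself lowers the number of calls. Cell type calls, 0, were 1 with the deposited table and 1 with all interactions. Diet by tissue calls, 48 (46 and 2), were 27 under normexp, 20 with the deposited table, 0 under spike-in scaling, 30 without the probe trend, 8 among the 88 and 82 with all interactions. Their split was 35 and 25 with the percentile over all miRNAs, 31 and 17 with quantile normalization, and 7 and 13 with the deposited table.

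Differences over 1 between single arrays were 5 in liver CD4 cells, and 0 under normexp, 9 with the total gene signal, 11 under spike-in scaling, 10 when scaled to T cell list miRNAs and 1 among the 88. In liver CD8 cells they were 40, and 25 with quantile normalization, 4 under normexp and 67 under spike-in scaling. In node CD4 cells they were 94, and 55 under normexp and 49 among the 88. In node CD8 cells they were 136, and 73 among the 88.

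Leaving out 1 array gave 0 to 25 diet calls (25 without high-fat liver CD4, 23 without normal-diet liver CD4, 16 without normal-diet liver CD8, 11 without high-fat liver CD8, 1 without normal-diet node CD4). It gave 43 to 96 tissue calls (43 without normal-diet liver CD8, 46 without normal-diet liver CD4) and 0 to 75 diet by tissue calls (0 without high-fat node CD8, 10 without high-fat node CD4, 75 without normal-diet node CD4). The array left alone in its diet and tissue was assumed to vary like the others.

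Reversed under normexp were diet miR-106b-5p (-0.12), miR-20a-5p (-0.15) and miR-20b-5p (-0.042), tissue miR-706 (0.37) and miR-712-5p (0.39), and cell type miR-5117-5p (-0.029). Cell type miR-466o-3p ran from -2.09 to 0.0013 when 1 array was left out (0.0013 without normal-diet node CD4), and miR-122-5p without both normal-diet node arrays (-0.21). Without those 2 arrays the diet medians of let-7 (-0.20) and miR-23/27/24 (-0.024) reversed, and the diet by tissue interaction could not be estimated. With matched pairs as blocks (the other 2 factors with their interaction, 3 residual degrees of freedom) limma called 0 miRNAs for diet (37 at an unadjusted p under 0.05), 68 for tissue (39 higher, 29 lower), all among the 80, and 0 for cell type (4 at an unadjusted p under 0.05). Signal over background limited the dimmest array most: normal-diet liver CD8 had 28 of 184 tested miRNAs at the floor, against 8 in normal-diet node CD4.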

Other observations

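The tests of explanations in this part were chosen after the results were seen, as was the list test on the tissue by cell type interaction. The counts of other splits were fixed before. The conditions that the order of detected miRNAs hold without each pair of arrays, that the marker difference hold without each array, and that the count between rows hold in 2 fits were added after those values were seen.

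MiR-155-5p, miR-21-5p and miR-146a-5p, the tested T cell activation miRNAs, had higher values of the liver against node difference in CD8 than in CD4 cells, although no member passed the test. The list median of that interaction was 1.54, with camera adjusted p = 0.00158, adjusted p = 0.584 with an estimated correlation and adjusted p = 0.853 in fry. This list was picked from tests of 11 lists on each of the 3 interactions, of which 2 passed camera here (regulatory T cell adjusted p = 0.0461), 6 for diet by tissue and 8 for diet by cell type. None of the 11 passed for any interaction with an estimated correlation (lowest adjusted p = 0.357) or in fry (lowest adjusted p = 0.0538). The lowest levels were those of the normal-diet node CD8 array, which stood apart on the first principal component (-28.0). MiR-155-5p had levels of 8.33 and 7.45 in high-fat and normal-diet liver CD8 cells and of 6.03 and 4.73 in node CD8 cells. In CD4 cells these were 8.14 and 7.62 in liver and 6.83 and 6.99 in node. MiR-21-5p had 12.17 and 10.69 in liver CD8 cells and 9.85 and 7.17 in node CD8 cells, and 11.36 and 10.87 in liver CD4 cells and 9.82 and 8.96 in node CD4 cells.

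The diet differences of the single pairs were compared across 88 miRNAs, which are not independent replicates. They ran together between node CD4 and node CD8 cells (Pearson r 0.76, Spearman rho 0.84, same sign in 79.5%) and between liver CD8 and node CD8 cells (0.55, 0.49 and 72.7%). Liver CD8 and node CD4 cells had 0.27, 0.24 and 65.9%. Liver CD4 cells had 0.05, 0.04 and 37.5% with liver CD8 cells, -0.23, -0.28 and 28.4% with node CD4 cells, and -0.30, -0.28 and 23.9% with node CD8 cells. No 2 of these pairs share an array. The same-sign shares depend on the scaling of the arrays. Median differences of the 88 miRNAs were 0.27 in liver CD4, -0.56 in liver CD8, -0.49 in node CD4 and -1.18 in node CD8 cells. A low share with liver CD4 cells can follow from these medians alone.

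MiR-451 and miR-223-3p were higher in liver cells, and RNA of other cells in the sorted pools is a candidate explanation, although sorting on CD4 and CD8 would remove most of them. A lower share of T cells that raised all other cell types alike cannot be told apart. MiR-122-5p differed by 1.17 (95% interval -0.26 to 2.60) and miR-451 by 4.34 (3.20 to 5.49), but miR-122-5p was detected on 1 of 4 node arrays. Without that array the differences were 2.06 (0.84 to 3.29) and 4.32 (3.29 to 5.34). Without the high-fat liver CD8 array they were 1.53 (0.025 to 3.04) and 4.29 (2.78 to 5.80). The intervals overlapped there and without the normal-diet liver CD8 array. MiR-148a-3p of the hepatocyte list passed as higher in liver (1.45, 0.31 to 2.58) near the floor. MiR-192-5p and miR-194-5p of the hepatocyte list went the other way, detected near the floor on the high-fat node arrays and on no liver array. Red blood cell or platelet RNA cannot be told apart, as 0 of the other miRNAs of that list were detected on a liver array and their abundance against miR-451 is not known here. Myeloid cells cannot be told apart either, as 0 other myeloid miRNAs passed the threshold, while miR-500-3p (2.10) passed only without the normal-diet node arrays. A difference between T cells of liver and node stays open and was not tested apart from these.

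MiR-10a-5p was detected on all CD4 and no CD8 arrays, and slide row is a candidate explanation because row and cell type coincide. A general row effect cannot be told apart from cell type: 1 of 184 miRNAs had an unadjusted p under 0.05 between rows, which was miR-10a-5p itself, but 19 did with all interactions in the fit. Lower sensitivity of the CD8 arrays cannot be told apart: a mean of 183.75 miRNAs was detected there and 175.5 on the CD4 arrays, but without the high-fat node pair the order turned (155 and 163). Each of these stays open beside a difference between the cell types, which is a hypothesis from these same data, and the difference did not pass adjustment over all miRNAs in the additive fit.

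Splits of the arrays into groups of 4, the real one included, gave as many calls as the real one in 2 of 33 cases for tissue (80 real, 82 highest other), so chance assignment was not excluded there. The split that gave 82 put both normal-diet node arrays with the high-fat node and liver CD4 arrays. Where the real split gave 0 calls, every split gives as many, so the count could not come out otherwise and says nothing about chance. These were 33 of 33 splits for diet (0 real, 72 highest other), 33 of 33 for cell type (0 and 49), 32 of 32 for the diet by cell type interaction (0 and 48) and 32 of 32 for the tissue by cell type interaction (0 and 48). The splits with 49, 48 and 48 calls are the diet by tissue grouping itself, high-fat node and normal-diet liver against the rest. The split with 72 set both normal-diet node and both liver CD4 arrays against the rest, which points to a structure of the arrays beyond diet.

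In the authors' deposited table, features without signal stood at a value that depended on the array, from -8.58 on the high-fat node CD8 array to -4.91 on the normal-diet liver CD8 array. A miRNA detected on neither array of a pair therefore differed between them in that table.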
